A study of Rattus norvegicus with 6 samples.

How the data were processed

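Rat primary beta cells, the insulin-secreting cells of the pancreatic islet, were purified by fluorescence-activated sorting in 3 batches. Each batch was transfected with 30 nM of a control siRNA or of an siRNA against Nova1 for 16 h and recovered for 48 h, per the labels' protocols. The 6 libraries were made from poly(A) RNA with an integrity number of at least 7.5, with products of 200 bp excised from a gel, and run on a HiSeq instrument, per the labels' protocols. Libraries were grouped and numbered by their titles, 3 control and 3 knockdown, and the number in a title is the batch.

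Reads were aligned with TopHat to the rat assembly Rnor_5.0, per the submitters' processing notes. The deposited assembly holds 60887 transcripts at 24102 loci, of which 30871 are new splice combinations of a known gene (class code j) and 30016 match a reference transcript, per the file contents. For every library the authors deposited an estimated read count, a length and an RPKM value (reads scaled to transcript length and library size) for each transcript, held as text attributes. The program that divided reads among transcripts, its version and its strand setting are not given in the sources used here. Between 18.2% and 18.8% of the read values above 0 in a library were whole numbers as written, with a tolerance of 0, and the others had a fractional part. Where transcripts of a gene share most of their sequence, an estimate at 0 can be a failed estimate, and such transcripts are described as listed at 0.

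Estimated reads were summed over the transcripts of each of 24579 gene models (a locus and a gene name). Names come from the assembly, and 517 of 5699 models named only by an identifier received a symbol from a RefSeq gene table on the assembly GRCr8, used for names only. The 5182 models left without a symbol were tested but are not named. Genes that share a name are printed with their locus identifier.

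The design written before the data were examined placed a count model first, with limma as the fallback where reads were held only as attribute text, and the fallback applied here. Reads were scaled by trimmed mean of M values (30% of M and 5% of A trimmed). Genes needed the equivalent of 10 reads in the library of median depth in at least 3 libraries and a total of at least 15 reads, which left 15983 genes. Voom in limma 3.58.1 (R 4.3.3) was fitted with batch as a block and group as the tested term, which leaves 2 residual degrees of freedom per gene, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. edgeR was not used as a count model for any reported value, because the reads are held as attribute text, but a trial of its quasi-likelihood test on the rounded reads with the same block called 0 genes. That trial was run outside the reproducible analysis, so its unadjusted counts are not given. DESeq2 was not run.

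Transcript shares were tested with limma diffSplice on a voom fit of the transcripts with the same scaling, filter and block (31429 transcripts of 9538 genes), with a test per transcript of departure from its gene and a Simes test per gene. Shares printed are percentages of the summed RPKM of the gene, as mean ± SD over 3 libraries. The 17 gene lists were fixed before the files were opened and tested with camera in limma at a preset correlation of 0.01, with an estimated correlation, and with fry. The lists hold 515 symbols, of which 498 matched. Overlaps were tested with a two-sided Fisher exact test.

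The batch numbers pair the libraries by design, and the data were checked for this. In gene-level log2 CPM, deviations from the group mean correlated between control and knockdown at 0.38, 0.72 and 0.55 in batches 1, 2 and 3. At that level each control resembled its own batch's knockdown more than any other library. In transcript shares this did not hold. Controls 1, 2 and 3 correlated most with another control, at 0.78, 0.742 and 0.78, against 0.762, 0.74 and 0.779 with their own knockdown. Nothing in the labels says whether the batches came from separate animals, so p-values measure the spread between these batches.

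Named genes follow a rule fixed beforehand. It takes Nova1, the 10 rising and 10 falling genes with the largest log2 fold change past the threshold, with the same direction in 3 batches and at least 1 RPKM in a group, up to 4 called members per list, and a fixed set of reference genes given whatever their result. Transcripts follow the same rule on the change in share, with 1 pair per gene. Some genes this rule takes are not reported here. Any other gene named was chosen after its values were seen.

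Alternatives set beforehand were no replicate block, leaving out each batch, median of ratios scaling or library totals alone, no filter or a filter 5 times stricter, limma-trend on log2(RPKM + 1), + 0.1 or + 0.01, diffSplice on log2(RPKM + 0.1), a Fisher exact test in each batch, and transcripts with at least 10% of their gene. Those added after seeing the data were limma-trend on log2 CPM, a correction for transcript length by a spline of 6 degrees of freedom per library, transcripts above 0 reads in all 6 libraries, and a test of cassette exon inclusion.

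The functions were tested on simulated libraries with the real means and depths and 200 changed genes. Among 15994 genes, limma voom recovered 96% of the genes changed 2-fold and 100% of those changed 3-fold, with 14 unchanged genes among 210 calls. Among 9744 genes tested for shares, the Simes test recovered 100% of genes with a transcript changed 4-fold and 99% of those changed 8-fold, with 6 unchanged genes among 205 calls. The simulation gave every gene the same noise, the median of the real genes, and the same fold in every batch, while real genes differ in both. It used this noise for transcripts as well, where it lies below the noise of real transcript estimates. The recovered percentages therefore do not give the power in the real libraries.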

Results

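RNA sequencing measured transcripts of purified rat beta cells after treatment with a control siRNA or an siRNA against Nova1, an RNA-binding protein of neurons that regulates alternative splicing. The title of the series concerns Nova1 and splicing in these cells, and the design compares both treatments within each of 3 batches. Control libraries held 292432076, 122637234 and 199930608 assigned reads in batches 1, 2 and 3, and knockdown libraries 130251486, 95394043 and 146453308, so the control was the deeper library of every batch. Ins1 and Ins2, the rat insulin genes, took 20.02%, 13.2% and 21.7% of control reads and 21.4%, 9.85% and 20.7% of knockdown reads. Batch 2 stood apart from the others, on a first principal component that held 55.1% of the variance, while the third component (11.6%) separated knockdown from control.

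Nova1 RNA was lower in the knockdown library of every batch. Its level was 19.8 ± 2.14 CPM (read counts scaled to library size; SD, n = 3) in control libraries and 9.13 ± 1.25 CPM in knockdown libraries. This is a log2 fold change of -1.12 (SE 0.11), or -54.0%, with an adjusted p of 0.038 in limma. The changes were -1.41, -1.08 and -0.88 in batches 1, 2 and 3. The gene lies on chromosome 6 between 76534363 and 76661158 of Rnor_5.0, on the minus strand. Nova2, its close relative, was measured at 7.94 ± 1.78 and 9.03 ± 1.09 CPM, a difference that did not pass the test (adjusted p = 0.24). Without the batch block the adjusted p for Nova1 was 1.00, it was 0.15 without batch 1 and 0.16 without batch 2, and it was 0.28 with limma-trend on log2(RPKM + 1), where the log2 fold change was -0.54.

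Knockdown libraries held more RNA for Lyz2, Col3a1, Col5a1 and Stradb, and less for Syncrip, Tmem9b and Slc35a2. Among 15983 genes tested, 82 rose and 192 fell at an adjusted p below 0.05, and all 274 moved the same way in 3 batches. A call in the blocked fit largely requires such agreement, so the agreement is not separate evidence. The trial of edgeR with the same block, the first choice of the design but run outside the reproducible analysis, called 0 genes. The changes were moderate, with a median size of 0.49 on the log2 scale, and 20 genes changed at least 2-fold. The smallest adjusted p was 0.036, so the 274 calls lay between that value and the threshold, and 3816 genes had an unadjusted p below 0.05. In limma 0 genes passed without the batch block (521 at an unadjusted p below 0.05), 0 without batch 2 (2796) and 0 with limma-trend on log2(RPKM + 1) (2763), while 4 passed without batch 1 (0 of them among the 274), 75 without batch 3 (45 of them) and 91 with library totals alone (47 up, 44 down; all among the 274).

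Col3a1 and Col5a1, of fibrillar collagen, rose by log2 fold changes of 1.26 (SE 0.15) and 1.12 (SE 0.10), from 4.86 ± 1.52 to 11.3 ± 1.04 CPM and from 4.04 ± 2.21 to 8.66 ± 4.29 CPM. Col5a2 rose by 1.02 on the log2 scale. Col4a1 and Col4a2, the basement membrane collagens, rose by 0.90 and 0.89. With the correction for transcript length, Col5a1 was at 1.00 and Col4a1 at 0.79, and both still passed. Col4a2 was at 0.79 with that correction and did not pass in limma (adjusted p = 0.054). Col3a1 and Col5a1 are members of the stellate cell and fibroblast list, which had a median of 0.39 and a camera adjusted p of 0.011 (adjusted p = 0.58 with an estimated correlation). The largest rise among genes with at least 1 RPKM in a group was in Lyz2, the macrophage lysozyme, at 1.43 (SE 0.17), from 2.81 ± 1.10 to 7.99 ± 4.75 CPM. Lyz2 is a member of the immune cell list, which had a median of 0.62 and a camera adjusted p of 0.0041 (adjusted p = 0.58 with an estimated correlation). Stradb, a pseudokinase partner of Stk11, rose by 0.91 (SE 0.07) from 16.6 ± 4.99 to 30.9 ± 7.53 CPM. Slc9a2, a sodium-proton exchanger, rose by 0.80, and Hells (XLOC_001702), a chromatin remodeller, by 0.81.

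The largest fall among genes with at least 1 RPKM was in Syncrip, an RNA-binding protein of the hnRNP family, with a log2 fold change of -3.64 (SE 0.33). Its control level was uneven, at 6.39, 1.74 and 24.5 CPM, against 0.92, 0.29 and 1.32 CPM in the knockdown. The log2 fold change was -2.74 without batch 3, and -3.99 and -3.76 without batch 1 or 2, where it did not pass (adjusted p of 0.12 and 0.16 in limma). Tmem9b, a transmembrane protein, fell by 1.06 on the log2 scale (SE 0.06), from 124.5 ± 34.3 to 60.6 ± 21.1 CPM. Slc35a2, the Golgi UDP-galactose transporter, fell by 0.94 (SE 0.06) from 40.6 ± 6.24 to 21.2 ± 4.50 CPM. Nxt2, an mRNA export factor, and Slc9a9, an endosomal sodium-proton exchanger, both fell by 0.93. Perp, a target of p53, fell by 0.91 and Swi5, of homologous recombination, by 0.86. Nicn1 fell by 0.86, and RPS29 (XLOC_008811), a ribosomal protein locus whose name occurs at several loci, by 0.93.

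**Figure D1:**
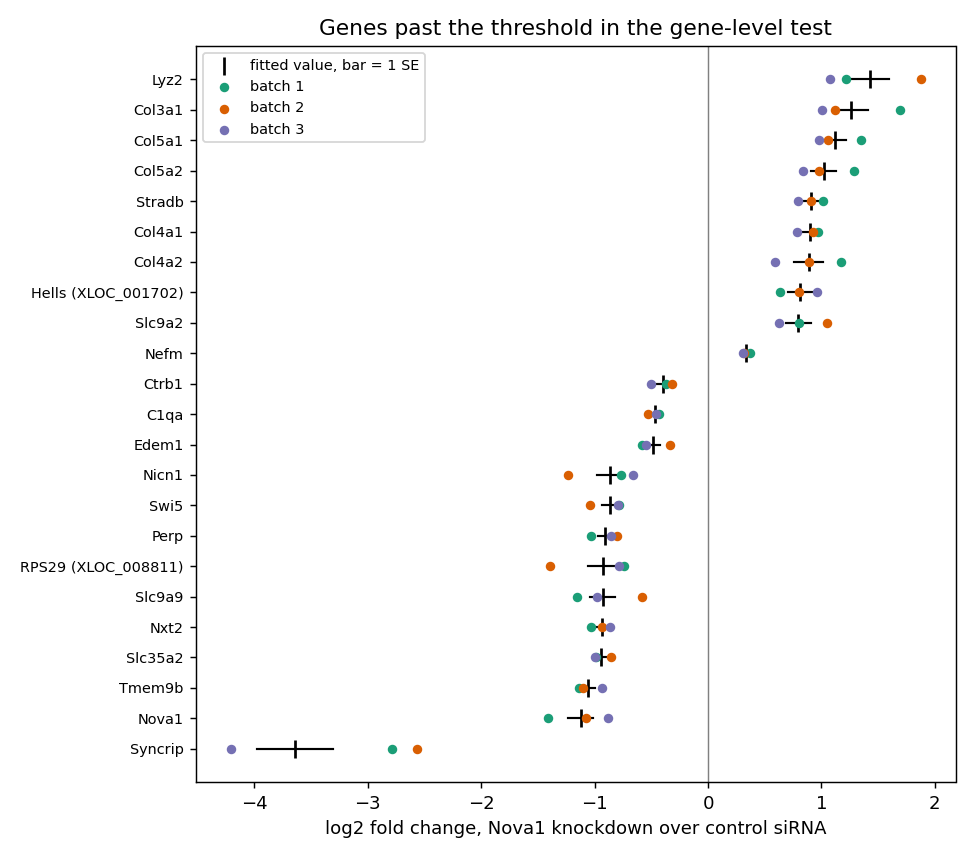
Log2 fold change of knockdown over control siRNA (x axis) for 23 genes past the threshold in limma, 1 per row; coloured points are the 3 batches, black ticks the fitted value and bars 1 SE. Nova1 sits at -1.12, Lyz2 at 1.43 and Syncrip at -3.64, and each gene keeps its sign in all batches, which a call in the blocked fit largely requires.

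Genes that define beta cells did not pass the test in either direction. None of the 30 tested members of the beta cell identity and hormone processing list passed the threshold, adjusted over all genes or over the list alone, and the list median was 0.02 (camera adjusted p = 0.29). Pdx1 was at 194.1 ± 11.7 and 196.8 ± 25.4 CPM in control and knockdown libraries. Ins1 and Ins2 had log2 fold changes of -0.21 (SE 0.12) and -0.17 (SE 0.13), with adjusted p of 0.32 and 0.46. Mafa varied most, from 0.96 in batch 1 to -1.70 in batch 2 (adjusted p = 0.77). Among the other reference genes, Gcg, the glucagon gene, had a value of 0.29 (adjusted p = 0.12), Sst -0.03, Snap25 -0.03, Plcb1 -0.19, Foxo3 0.20 and Bcl2l11 0.19, and none passed. With the correction for transcript length, added after seeing the data, Plcb1 was at -0.33 and Gcg at 0.36, and both passed in limma (adjusted p of 0.033 and 0.0496). Exocytosis machinery (50 members tested, median 0.01), endoplasmic reticulum stress (25, 0.01) and apoptosis (34, -0.03) had camera adjusted p of 0.84, 0.98 and 0.29. No exocytosis gene was called over all genes or adjusted over the list alone. Edem1, which directs misfolded proteins to degradation, was the called member of the stress list by both adjustments (1 down adjusted over the list alone) and fell by 0.49 on the log2 scale, from 195.2 ± 25.5 to 140.7 ± 30.8 CPM. The apoptosis list had an adjusted p of 0.045 in fry, in the direction of lower expression, with 0 members called over all genes and 1 member up and 2 down adjusted over the list alone.

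Acinar genes, which encode digestive enzymes, were lower in the knockdown libraries as a list. Of 23 tested members, 22 had a negative log2 fold change, 1 was called and 14 fell adjusted over the list alone. The median was -0.42, at -0.37, -0.49 and -0.41 in batches 1, 2 and 3, and the camera adjusted p was 9.63e-09 (adjusted p = 0.35 with an estimated correlation, 0.045 in fry). Ctrb1, chymotrypsinogen, fell by 0.40 from 143.6 ± 55.3 to 110.2 ± 45.7 CPM. With the length correction Ctrb1 was at -0.31 and did not pass in limma (adjusted p = 0.055). Cpa1 and Prss1, chosen after their values were seen, had log2 fold changes of -0.46 and -0.51 with adjusted p of 0.051 and 0.055.

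Lists of brain Nova targets and ion channels had higher values in the knockdown. Of 34 tested brain splicing targets of Nova proteins, 28 had positive values, the median was 0.18 and the camera adjusted p was 3.97e-04 (adjusted p = 0.58 with an estimated correlation). Only Nova1 itself was called among them over all genes, while 10 rose and 1 fell adjusted over the list alone. Of 53 tested ion channels of the beta cell, 38 were positive with a median of 0.14 and a camera adjusted p of 4.56e-04 (adjusted p = 0.58 with an estimated correlation). None was called over all genes and 10 rose adjusted over the list alone. Gria2, a glutamate receptor subunit in both lists, had a value of 0.41 with an adjusted p of 0.056, and Hcn4 had 0.31 with 0.056; both were chosen after their values were seen. Longer transcripts had higher fold changes across the 15983 genes (Spearman rho 0.32; genes are not independent replicates), with rho of 0.04, 0.37 and 0.34 in batches 1, 2 and 3. Members of the Nova target and ion channel lists had median lengths of 5307 and 5433 nt, against 2389 nt for all genes tested. With the length correction their medians were 0.11 and 0.04 (camera adjusted p of 0.025 and 0.036 at the preset correlation). The trend also ran through the called genes, with a median length of 4597 nt for the 82 that rose and 2120 nt for the 192 that fell.

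Insulin and PI3K signalling genes were positive in 25 of 37 tested members, with a median of 0.09, a camera adjusted p of 0.0041 (adjusted p = 0.58 with an estimated correlation) and none called by either adjustment. Insr, the insulin receptor, had a log2 fold change of 0.34 (SE 0.08, adjusted p = 0.10), and the median length in this list was 5526 nt. With the correction for transcript length the camera adjusted p of this list was 0.21. Immune cell markers were positive in 13 of 15 tested members, with a median of 0.62 and a camera adjusted p of 0.0041 (adjusted p = 0.58 with an estimated correlation). Lyz2 rose as given, while C1qa, a complement component, fell by 0.47 on the log2 scale from 10.7 ± 0.96 to 7.73 ± 0.96 CPM; 5 rose and 1 fell adjusted over the list alone. Stellate cell and fibroblast genes were positive in 11 of 15 with a median of 0.39, at 0.80, 0.91 and -0.01 in batches 1, 2 and 3. Their camera adjusted p was 0.011 (adjusted p = 0.58 with an estimated correlation), with Col3a1 and Col5a1 called over all genes and 6 up and 1 down adjusted over the list alone. Without batch 2 the camera adjusted p was 0.066.

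Cell cycle genes were negative in 20 of 26 tested members, with a median of -0.15, a camera adjusted p of 0.037 (adjusted p = 0.58 with an estimated correlation), none called over all genes and 4 down adjusted over the list alone. The camera adjusted p was 0.076 without batch 2 and 0.20 without batch 3. The RNA-binding splicing regulators had a median of 0.05 over 83 members (camera adjusted p = 0.11), with Nova1 the called member. Adjusted over the list alone, 1 more rose. Other islet endocrine cells (median 0.15, adjusted p = 0.19), duct cells (-0.02, 0.94), endothelial cells (0.07, 0.98), interferon response (-0.11, 0.27) and neurons and Schwann cells (0.01, 0.88) did not pass. With the length correction the other islet endocrine list passed, with a median of 0.15 and a camera adjusted p of 0.032 at the preset correlation (without the length correction, adjusted p = 0.58 with an estimated correlation and 0.43 in fry). Adjusted over the list alone, 1 duct gene rose, 1 interferon gene fell, 2 neuronal genes rose and 1 fell, and 0 of the endocrine and endothelial genes passed. The mean had the opposite sign of the median in the duct (0.07), endothelial (-0.03), neuronal (-0.03) and endoplasmic reticulum stress (-0.01) lists, and the camera test of the endothelial and stress lists pointed down. In the neuronal list Nefm, the medium neurofilament, rose by 0.33 (SE 0.05) from 47.2 ± 5.76 to 59.5 ± 7.08 CPM. With the length correction Nefm was at 0.22 and did not pass in limma (adjusted p = 0.14).

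**Figure D2:**
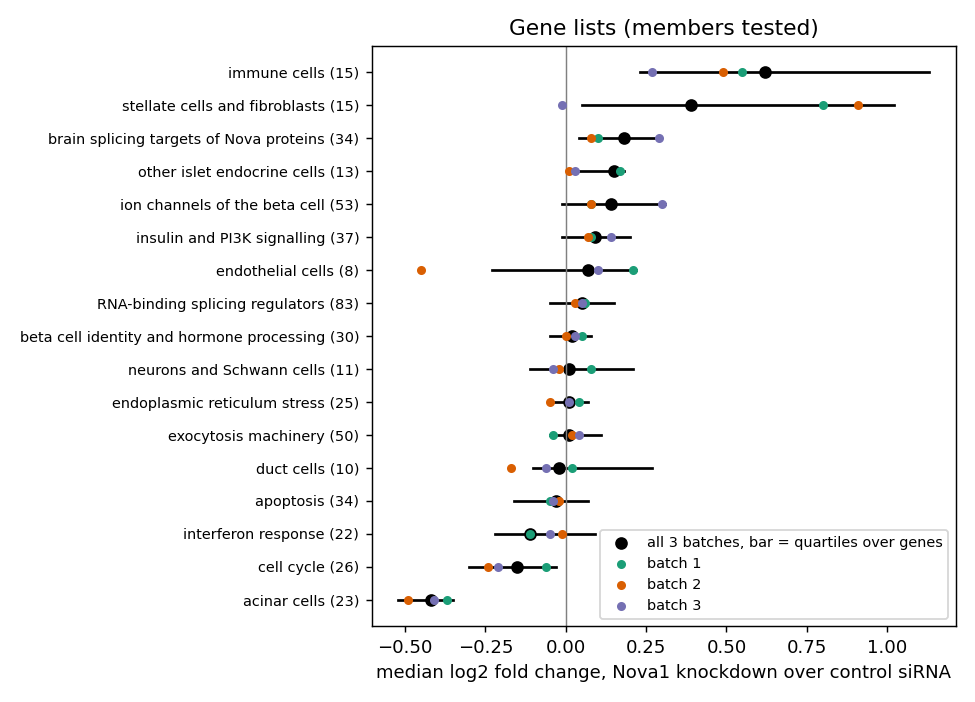
Median log2 fold change of knockdown over control siRNA (x axis) for the 17 gene lists, with the number of members tested; black points cover all batches, bars are the quartiles over member genes and coloured points the medians within batches. The acinar list lies lowest at -0.42 and the immune list highest at 0.62.

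The relative use of transcripts within a gene changed in 67 of 9538 genes tested and for 97 of 31429 transcripts, of which 48 rose and 49 fell (limma diffSplice, adjusted p below 0.05). Itga3, the alpha-3 integrin subunit, showed the largest fall in share among genes with a symbol and at least 1 RPKM. Its main transcript in control libraries fell from 93.9 ± 0.24% to 4.52 ± 0.72% of the gene's RPKM (SD, n = 3), and another rose from 4.17 ± 1.44% to 87.5 ± 4.01%, both with an adjusted p of 0.0032. The rising transcript carries a 141 bp internal exon on chromosome 10 between 82668800 and 82668940 of Rnor_5.0, and it also differs in the first exon. Inclusion of this exon was also taken as a percentage of the RPKM of only those transcripts that include it or skip it between the same flanking exons. It was 5.85%, 6.10% and 6.32% in control and 94.6%, 96.1% and 95.1% in knockdown libraries of batches 1, 2 and 3. The adjusted p was 0.24 in the limma test of cassette exons added after seeing the data. Cwc22, a spliceosome factor, moved from a transcript at 87.0 ± 2.64% to a share of 3.69 ± 3.20%, while a transcript listed at 0 in the controls reached 84.2 ± 1.24% (adjusted p of 0.033 and 0.011). Of called transcripts, 48.5% were listed at 0 in at least 1 library against 34.7% of tested ones, and 91 transcripts were at 0 in all libraries of a group and above 1 CPM in all of the other, against up to 93 when control and knockdown were exchanged within batches. Without batch 1, 2 or 3 the calls numbered 486, 428 and 509 transcripts, of which 54, 60 and 58 were among the 97. The limma test of cassette exons called 0 of 4381 (202 at an unadjusted p below 0.05).

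In several further genes a transcript changed its share. Atad3a, of the mitochondrial inner membrane, had a transcript rise from 24.8 ± 10.4% to 89.6 ± 0.06% and its partner fall from 75.2 ± 10.4% to 10.4 ± 0.06%. Zfp609, a transcriptional cofactor, fell from 100% to 43.1 ± 3.36% for a transcript and rose from 0 to 56.9 ± 3.36% for the other. Cog2, of the Golgi tethering complex, fell from 98.3 ± 0.76% to 38.4 ± 6.55%, and a transcript listed at 0 rose to 50.9 ± 9.66%. Ndst4, a heparan sulfate enzyme, moved to a transcript with an internal exon of 1217 bp (chromosome 2, 248550827 to 248552043), from 20.9 ± 18% to 100%. Orc2, of the origin recognition complex, had a transcript at 10.6 ± 1.98% and 61.0 ± 4.42%, and Zfp418 had a transcript with a 39 bp exon at 16.0 ± 6.93% and 66.7 ± 6.34%. Strbp and Tbxas1 each had a transcript listed at 0 in controls that reached 75.7 ± 5.38% and 60.1 ± 14.0%. The partners of these transcripts did not pass in limma (adjusted p of 0.074 for Strbp and 0.27 for Tbxas1). Pairs that differed in the first exon were close in length for Strbp (3068 and 3065 nt), Zfp609 (8451 and 8479 nt) and Cwc22 (3097 and 3134 nt). How much sequence each pair shares was not measured. Transcripts of Lmo4, Zfand4, Nfe2l1 and Socs7 fell, from 97.1 ± 0.90% to 25.3 ± 2.74% for Lmo4 and from 70.3 ± 17.9% to 5.10 ± 0.12% for Nfe2l1. In Zfand4 the share went from 69.0 ± 20.4% to a listed 0, and in Socs7 from 71.2 ± 8.01% to 11.5 ± 7.95%. Over the 67 genes, the pair compared differed in the first exon in 36, in the last exon in 12, by a cassette exon in 8 and in other internal splice sites alone in 12, and the pair had the same introns in 5. Zfp418 and Zfand4 are not among them, with adjusted p of 0.051 and 0.069 for the gene. The transcript call was lost whichever batch was left out for Orc2 (adjusted p of 0.052 to 0.081), Atad3a (0.058 to 0.14) and Socs7 (0.064 to 0.15), and it was lost for Lmo4 without batch 1 or 2 (0.16, 0.23), Tbxas1 without batch 1 or 3 (0.096, 0.11) and Zfp418 without batch 2 or 3 (0.21, 0.19). Without the batch block Orc2 and Zfp609 did not pass (0.11, 0.068). With the strict filter the calls of Ndst4 (0.12), Strbp (0.15), Zfp609 (0.11), Zfp418 (0.11), Tbxas1 (0.060), Orc2 (0.052) and the falling transcript of Cwc22 (0.088) were lost. Among transcripts with a share of at least 10%, those of Nfe2l1 (0.25), Zfand4 (0.17), Socs7 (0.28), Zfp418 (0.11) and Orc2 (0.10) were lost. Both transcripts of Itga3 and of Cog2 passed in limma in all of these settings (adjusted p of 1.16e-04 to 0.038).

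**Figure D3:**
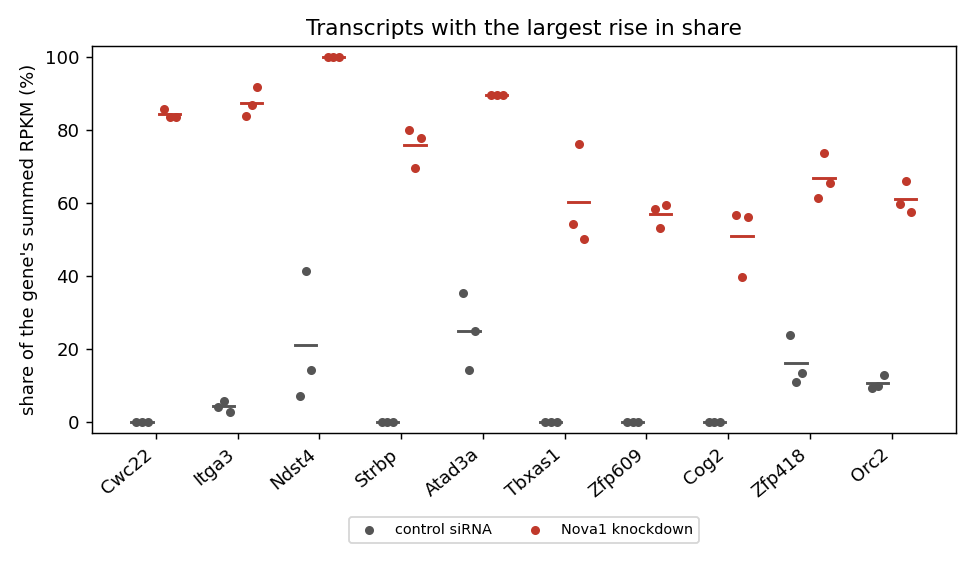
Share of the gene's summed RPKM in percent (y axis) of the 10 transcripts with the largest rise; points are libraries, horizontal bars means, grey control siRNA and red Nova1 knockdown. The Itga3 transcript lies at 4.17% and 87.5%, and 5 of the 10 transcripts are at 0 in every control library.

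Among the fixed lists, beta cell identity held the most genes with changed transcript shares. These were Pax6, a transcription factor of islet cells, and Gipr, the GIP receptor, or 2 of 23 tested members (Fisher exact adjusted p = 0.19). A Pax6 transcript fell from 19.5 ± 0.58% to 10.5 ± 1.61% (adjusted p = 0.0082), with a partner that differs in its first exon, and it did not pass without the batch block (adjusted p = 0.26). A Gipr transcript fell from 87.6 ± 6.16% to 50.9 ± 25.6% (adjusted p = 0.043), by -43.8, -64.2 and -2.35 points in batches 1, 2 and 3. This call was lost without the batch block (adjusted p = 0.79), without batch 1 (0.13), without batch 2 (0.41) and on log2(RPKM + 0.1) (0.37). Col3a1 was the called member of the fibroblast list, with a transcript at 43.9 ± 13.1% in controls and listed at 0 in the knockdown (adjusted p = 0.055 for the transcript). That transcript and its partner were 4761 and 4765 nt long. Of 30 tested brain splicing targets of Nova proteins, 0 were called and 1 had an unadjusted p below 0.05 in the Simes test. Over all 9538 genes tested, 67 were called and 1167 had such a p. No list passed the Fisher exact test. Few genes changed both in shares and in total expression. In 9538 genes tested both ways 1 gene was called by both, where 1.48 are expected by chance (Fisher exact p = 1, odds ratio 0.67, 95% interval 0.017 to 3.91).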

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

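Length correction, limma-trend on CPM, the limit to transcripts above 0 and the cassette exon test were chosen after seeing the data. The number of changed genes (274) depended on most choices. It was 0 with no replicate block, 0 to 75 with a batch left out, 171 with no filter and 119 with the strict filter. It was 72 with limma-trend on log2 CPM and 0 with limma-trend on log2(RPKM + 1), + 0.1 or + 0.01. The length correction gave 609, with 134 up and 475 down, and 252 of the 609 were among the 274. Library totals alone gave 91, with 47 up and 44 down in place of 82 and 192, and shifted the median of all genes to 0.058. Nova1 was lower in every fit, at -1.12 with no replicate block, -1.25 to -0.98 with a batch left out and -0.54, -0.73 and -0.76 on log2 RPKM with 1, 0.1 and 0.01 added, but it missed the threshold in these RPKM fits, with no block and without batch 1 or 2. Changed transcripts (97) numbered 428 to 509 with a batch left out (54 to 60 of them among the 97), 192 with no filter and 43 with the strict filter. They numbered 58 above a 10% share, 41 above 0 reads in all 6 libraries (24 of them among the 97) and 4940 by Fisher's exact test in each batch. As cassette exons in limma, 0 of 4381 passed (202 at an unadjusted p below 0.05). Genes with changed shares (67) numbered 281 to 322, 138, 28, 34, 22 and 3052 in the same order, and 40 on log2(RPKM + 0.1). With no replicate block there were 108 transcripts and 84 genes with changed shares, of which 62 and 47 were among the original calls. In place of 7 gene lists, 0 passed with an estimated correlation and 2 in fry, of which 1 was among the 7. Small values of genes that were not called changed sign: Snap25 to 0.0257 with library totals and to 0.0193, 0.0194 and 0.0194 on log2 RPKM with 1, 0.1 and 0.01 added, and Sst to 0.0266, to 0.0194, 0.0195 and 0.0195, and to 0.093 with the length correction. With a batch left out they ranged from -0.31 to 0.024 for Ins2, -0.023 to 0.078 for Pdx1, -0.85 to 0.43 for Mafa, -0.061 to 0.0082 for Snap25 and -0.16 to 0.12 for Sst. The cause of these differences was not tested, apart from fewer libraries or genes where these were removed. Over the named genes other than Nova1 and the alternatives, 243 values kept their direction and side of the threshold and 167 kept the direction but no longer passed. For named transcripts these counts were 205 and 50. The 243 include the reference genes, which had not passed and so had no call to lose. All 167 losses therefore fell on called genes, and the 243 overstate how stable those calls were. A trial of edgeR, the first choice of the design but not part of the reproducible analysis, called 0 genes. DESeq2 was not run, quantile normalization applied only to an RPKM main test, and the overlap of calls has no value in fits with 0 genes. Each library held 95394043 assigned reads or more.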

Other observations

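The tests of batch medians, of the acinar quartile, of on and off transcripts, of cassette exons and of the splits were chosen after the result was seen, and the length correction and the limit to transcripts above 0 reads after the data were seen but before their own results.

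Internal exons that can be skipped were compared one by one, and 0 of 4381 passed in limma (202 at an unadjusted p below 0.05). The exons given here were chosen after their values were seen. Cpsf1, a factor of mRNA 3' end processing, had a 272 bp exon included at 44.0%, 58.2% and 65.3% in controls and at 7.53%, 15.2% and 10.5% in knockdown libraries of batches 1, 2 and 3. Raph1, an actin regulator, had an 81 bp exon at 68.6%, 57.7% and 51.1% and at 94.5%, 94.7% and 93.4%. Cxxc4, an inhibitor of Wnt signalling, had a 76 bp exon at 99.8%, 99.4% and 99.4% and at 70.2%, 82.2% and 72.1%. The adjusted p of these 3 exons was 0.86.

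Lists of long genes were higher in the knockdown, and a length trend between libraries could produce this. After removal of that trend the brain Nova targets kept a median of 0.11 (0.18 before), with a camera adjusted p of 0.0247 at the preset correlation. A positive median was thus left after the correction. The estimated correlation of this list was 0.20 against the preset 0.01, and the corrected list was not tested with the estimate. The adjusted p therefore cannot decide whether length was the whole cause for this list. The ion channel list had an adjusted p of 0.0361 but a median of only 0.04 (0.14 before), so length and an effect of the knockdown cannot be told apart for it, since most of the median went with the correction. Its medians before the correction were 0.08, 0.08 and 0.30 in batches 1, 2 and 3. The test of the lowest, 0.08, was chosen after these were seen, so it cannot decide whether batch 3 carries most of the trend. The uncorrected list passed without batch 1, 2 or 3 at the preset correlation (camera adjusted p of 1.33e-05, 0.0017 and 0.0095), so that call did not rest on batch 3 alone. The corrected list was not tested by batch. Neither list passed with an estimated correlation (adjusted p = 0.58 for both), and an effect of Nova1 on these genes stays open as a hypothesis.

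Acinar genes were lower together, and length as the whole cause is argued against by an adjusted p of 1.65e-06 and a median of -0.35 after the correction, although the uncorrected call was lost with an estimated correlation (adjusted p = 0.35). Fewer acinar cells in the knockdown samples may explain it, but this stays open, since the high quartile of the list, -0.35, only restates that 22 of 23 members were negative. Sorting of beta cells should remove acinar, immune and stellate cells alike, yet Ctrb1 and Cpa1 were at 143.6 and 57.5 CPM in controls. The immune and stellate lists had medians of 0.62 and 0.39 (stellate -0.01 in batch 3) and the acinar list -0.42, so these lists did not move together. Gcg was at 8837 CPM in controls and had a log2 fold change of 0.29 (adjusted p in limma of 0.12, and 0.0496 with the length correction). Opposite changes in minor cell types do not show whether beta cell purity changed, so this stays open. More immune or stellate cells in the knockdown samples, which bears on the rises of Lyz2, Col3a1 and Col5a1, and an effect of Nova1 within any of these cells were not tested and stay open.

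Changed transcript shares may come from reads that pass between similar transcripts in the estimates. The 41 calls left among transcripts above 0 reads in all 6 libraries do not decide this, since 47 of the 97 called transcripts were at 0 in at least 1 library and were removed whatever the cause. Transcripts at 0 in a group and above 1 CPM in the other numbered 91, against 70, 90 and 93 in the other splits that part each pair, so switches of this kind were as frequent without the knockdown contrast. Changes of at least 30 points without overlap numbered 63, against 22, 37 and 38 in those splits and 50 to 65 in the 6 splits that part 1 pair, 2 of which had 65, and an effect of Nova1 on splicing stays open. Both Itga3 transcripts were above 0 reads in every library, so they were not of the on and off kind. Both passed in limma among transcripts above 0 reads (adjusted p of 0.0028 and 0.0022). Reads can also pass between transcripts above 0, so no single gene here, Itga3 included, can be assigned to either cause from these estimates.

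The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 274 changed genes, and the highest other gave 1, so 1 of the 10 splits reached the real count. For transcripts it gave 97 against a highest other of 243, and 3 of 10 splits reached it, and for genes with changed shares 67 against 155, with 3 of 10. The 243 and 155 came from a pair of splits that part only the libraries of batch 1, so with the block both rest on that batch alone and are the same contrast. Of the 4 splits that part every pair, the others gave at most 0 genes (211 at an unadjusted p below 0.05 in limma voom), 46 transcripts and 27 genes with changed shares.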
